A study of Drosophila melanogaster with 3 samples.

How the data were processed

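Total RNA from 3 samples of OSS cells, a stable somatic line derived from the Drosophila melanogaster ovary, was hybridised to Affymetrix GeneChip expression arrays after conversion to biotin-labelled cRNA, per the labels' protocols. All samples belonged to 1 group, grown without added treatment, and no other condition was labelled, so no comparison between conditions was made. The labels do not say whether the 3 samples came from separate cultures, so every SD and limma p-value measures only the spread between these samples, which may be technical.

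The deposited values were log2 expression levels per probe set and array; the log base was taken as 2 from their range and was not given in the sources used here. The labels say only that scanner files entered custom scripts, and the background correction, scaling and summary method were not given in the sources used here. The table held 18952 probe sets for each of the 3 arrays. Values ran from 2.39, a lowest value shared by all arrays, to 14.75. The array medians were 2.399, 2.401 and 2.399, so values were used as deposited, by a rule set before the data were examined. Values identical to every deposited digit on all 3 arrays occurred in 12735 probe sets (67.2%), of which 6891 lay at the lowest value. An SD of 0 therefore describes the deposited summaries and understates the measurement error. Among probe sets with means over log2 4 that were not identical on all 3 arrays, 26.1% were identical on exactly 2. The SDs of such probe sets, such as 0.00059 for cos, may understate the error too. The 3 arrays were not copies of each other, since Pearson correlations across probe sets were 0.995, 0.988 and 0.986. The number of arrays limits the precision.

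Probe sets were named through the platform's annotation. Symbols were compared by gene identifier with the RefSeq gene table of Drosophila melanogaster assembly Release 6 plus ISO1 MT. Of 13647 single-gene probe sets 13544 matched it, and 0 symbols changed. A further 402 probe sets carried several genes and 4903 were not listed, of which 183 were array controls; none of these entered the gene results. The 13647 probe sets named 11982 genes. Of 1094 genes with several probe sets, each took the probe set with the highest mean; in 174 of them one probe set lay over 1 log2 unit above background and another at or under background. Genes of the lists without a single-gene probe set in the annotation used, among them Fas3, AGO1, AGO2 and N, were not analysed here, and no transposable element of the list was matched by name. No coordinates are given, because the genome build behind the deposited files was not given in the sources used here.

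The background level was the 95th percentile of the mean values of 112 odorant and gustatory receptor genes, chemosensory genes taken as unused in these cells. It was 2.49. Each gene's 3 values were tested against it with limma 3.58.1 in R 4.3.3 (intercept-only lmFit and eBayes, one-sided for above and for below, Benjamini-Hochberg adjustment over all genes each way). A gene was called above or below background at an adjusted p under 0.05 and unresolved otherwise. Most genes had an SD of 0, for which limma's variance moderation is unreliable, so an alternative estimated the spread from the other genes. These still include genes with identical values on 2 arrays, so that spread may be too small as well. SDs of identical values that computer rounding left just above 0 were set to 0; this step was added after a first fit had been seen, and it changed the number of calls. In simulated data on the 11982 genes, 74% of 50 genes set 0.25 log2 units above background were called above, 82% at 0.5, 92% at 1 and 100% at 2. The simulated SDs were drawn from genes over the background level, including those with an SD of 0. These shares may therefore overstate the sensitivity of the calls.

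Gene lists were fixed before the data were examined. The share of each list above background was compared with that of all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 25 lists. Pairs of lists were compared by Fisher's exact test, two-sided, adjusted over the 2 pairs. A planned permutation test of the difference of the lists' median levels was computed and is not used here, because probe sets differ in affinity and a higher value of one gene than another does not measure more transcript. Calls against 1 background level depend on affinity too, and genes are not independent replicates.

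Genes named were 15 measured genes of the pathway and of cell identity fixed in advance (piwi, fs(1)Yb, zuc, armi, vret, shu, aub, AGO3, vas, spn-E, rhi, tj, nanos, osk and bam), the 3 highest and 3 lowest members of the 6 main lists, the 2 highest and 2 lowest of every other list, the 10 genes with the highest mean outside ribosomal proteins, and the 5 genes above background with the largest SD. Other genes named were chosen after their values were seen.

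Alternatives planned were other background lists (odorant receptors, gustatory receptors, testis genes, bacterial poly-A control probe sets), the 90th and 99th percentiles, quantile normalization, median centring, other treatments of several probe sets or several genes, and leaving out each array. Alternatives added after seeing the data were 115 control probe sets of other foreign sequences and tags as background (hybridisation controls left out), the pooled spread, the highest background gene as level, and a level 1 log2 unit above background, called the stricter level below. A planned filter on dim probe sets removed 0 of them, and a planned pseudocount did not apply to log values. Gene families described among the other observations were chosen after the data were seen. The planned comparison of levels with 3′ UTR length was not run because no UTR annotation was used here.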

Results

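Expression was profiled in OSS cells, a somatic line of the Drosophila ovary that the labels trace to follicle stem cells, on 3 arrays of 1 group. The series' title names a primary piRNA pathway in ovarian somatic cells, so the comparisons concerned which genes of that pathway, and of cell identity, had signal above that of genes not used in these cells. Of 11870 named genes outside the background list, 5582 (47.0%) were above background, 5892 were below it and 396 were unresolved (limma, adjusted p under 0.05). At the stricter level, 1 log2 unit higher, 3028 genes were above. Of the 112 chemosensory receptors that set the background level, 5 were called above it, with Gr39a at 2.79 and Gr61a at 2.61 the highest and Or98a and Or9a at the shared lowest value of 2.39. Of the array's control probe sets, 0 of 27 bacterial poly-A controls and 6 of 115 for other foreign sequences and tags were over the background level, the highest of these at 3.17. Another 20, for E. coli bio genes and phage P1 cre, were taken as hybridisation controls and left out of both sets; 19 of them were over it, up to 13.92.

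Across probe sets, Pearson correlations were 0.995 between replicates 1 and 2, 0.988 between 1 and 3 and 0.986 between 2 and 3. Spearman correlations were 0.988, 0.992 and 0.987. Of the genes above background, 29.1% had identical values on all 3 arrays, and the median SD of the others was 0.13 log2 units. The highest means outside ribosomal proteins, which do not rank transcripts because probe sets differ in affinity, were those of CG5953 at 14.56 ± 0.20, the chaperone Hsc70-4 at 11.58 ± 0.31 and the translation factor eEF5 at 11.57 ± 0.55 (SD, n = 3). CG14072 measured 11.45 ± 0.55, CG31676 11.42 ± 0.40 and CG4789 11.20 on every array. The cofilin gene tsr measured 11.03 ± 0.41, the small heat shock gene l(2)efl 10.94 ± 0.054 and Tctp 10.94 ± 0.48. Arc1 measured 10.96 on every array with 1 probe set and 9.02 ± 1.63 with the other.

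Genes of the primary piRNA pathway were above background throughout. All 13 measured members passed the test, both over all genes and adjusted over the list alone, against 47.0% of other genes (Fisher's exact test, two-sided, adjusted p = 0.00045). The RNA helicase gene armi measured 7.49 ± 0.54 (SD, n = 3), and piwi, which encodes the nuclear Argonaute protein of the pathway, measured 6.47 ± 0.50. The Tudor-domain genes papi and vret measured 6.05 on every array and 5.66 ± 0.13. The gene fs(1)Yb, whose protein marks the somatic Yb bodies, measured 4.55 ± 0.32 and the co-chaperone gene shu 3.87 ± 0.086. Levels near background were found for daed at 2.94, the nuclease gene zuc at 2.78 and SoYb at 2.65 ± 0.0027. With the highest background gene, Gr39a at 2.79, as level, 11 of the 13 were above, and zuc and SoYb lay under it. At the stricter level 8 of the 13 were above (Fisher's exact test, adjusted p = 0.040).

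Of 9 measured genes for factors of Piwi-directed transcriptional silencing, 8 were above background, also when adjusted over the list alone, and wde was unresolved at 2.71 ± 0.24 (SD, n = 3). The listed genes arx and egg were not analysed here. The gene of heterochromatin protein HP1a measured 9.25 ± 0.26, the RNA export cofactor gene Nxt1 8.29 ± 0.22 and ctp, a dynein light chain gene, 6.08 ± 1.29. Panx measured 3.07 ± 0.063 and the demethylase gene Su(var)3-3 3.64 ± 0.027. The highest of the control probe sets for other foreign sequences and tags, at 3.17, lay over Panx. Without replicate 1, ctp was not called (limma, adjusted p = 0.091). The list's share exceeded that of other genes (Fisher's exact test, adjusted p = 0.039), and 6 of 9 were above at the stricter level (adjusted p = 0.046). Without replicate 1, 77.8% were above and the list missed the threshold (adjusted p = 0.11); with the bacterial controls as background its adjusted p was 0.099.

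Germline factors of the ping-pong cycle and of dual-strand clusters were split. Of 16 measured genes, 10 were above background, 5 below and 1 unresolved, a share not shown to differ from other genes (62.5% against 47.0%, Fisher's exact test, adjusted p = 0.49); adjusted over the list alone, 10 were above. The Tudor-domain helicase gene spn-E measured 6.95 ± 0.37 (SD, n = 3) and the Tudor-domain gene krimp 4.98 ± 0.63, the only members above at the stricter level. The next, tud, measured 3.40 ± 0.069. The Argonaute gene aub was 0.31 log2 units above background at 2.79 on every array. Gr39a, a receptor gene of the background list, also measured 2.79. With Gr39a as level, aub was not called (limma, adjusted p = 0.067) and 5 of the 16 genes were above. AGO3, the helicase gene vas and tej lay at the shared lowest value of 2.39 on every array, and rhi, which encodes the cluster chromatin protein Rhino, also measured 2.39.

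The primary list had the larger share above background than the germline list, 13 of 13 against 10 of 16, a difference of 37.5 percentage points (Fisher's exact test, two-sided, adjusted p = 0.041). At the stricter level the counts were 8 of 13 against 2 of 16 (Fisher's exact test, adjusted p = 0.032).

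**Figure D1:**
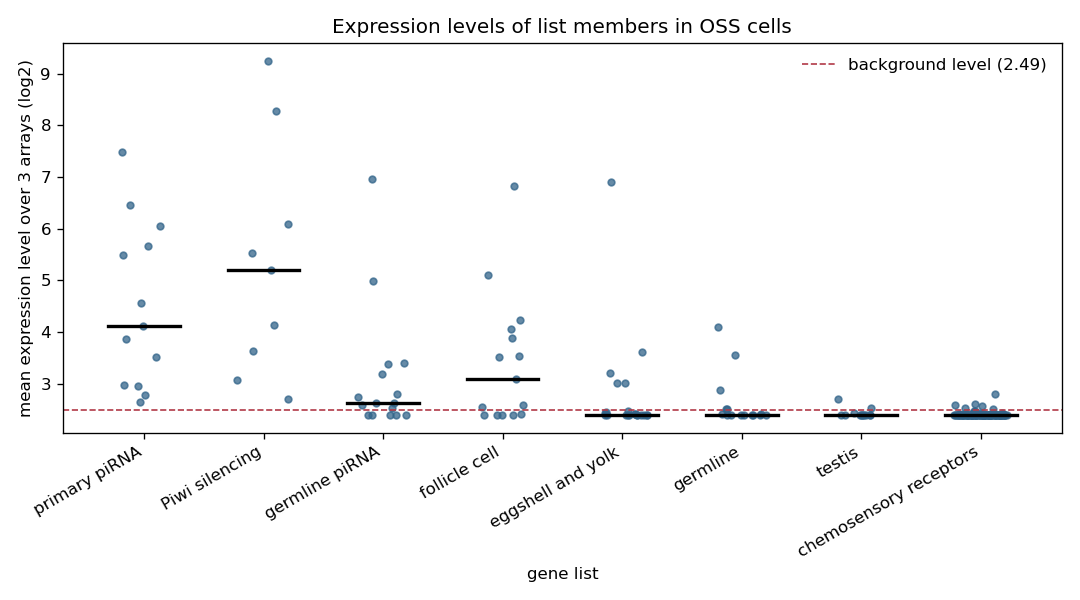
Mean log2 expression level over 3 arrays (y axis) of each measured member of 8 gene lists (x axis); points are genes, black bars list medians and the dashed line the background level of 2.49. All 13 members of the primary piRNA list lie above the line, and 10 of 16 of the germline piRNA list were called above it.

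The labels trace the line to follicle stem cells and name Fas III as its marker, and the cell identity lists addressed this; Fas3 itself was not analysed here. Of 15 follicle cell genes, 9 were above background, 5 below and 1 unresolved, with 9 above when adjusted over the list alone. The transcription factor gene tj, a marker of ovarian somatic cells, measured 6.83 ± 0.69 (SD, n = 3), zfh1 5.10 ± 0.25 and Egfr 4.22 on every array. The members with the lowest values were cas, peb and slbo, at 2.39 on every array. The list's share of 60.0% was not shown to differ from other genes (Fisher's exact test, adjusted p = 0.65). Without replicate 1, 6 of the 15 were above.

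Germline markers were mostly below background: 10 of 15 were below, 4 above and 1 unresolved, with 4 above when adjusted over the list alone (26.7% above, Fisher's exact test, adjusted p = 0.21). The germline stem cell and oocyte genes nanos, bam and osk measured 2.39 on every array, as did orb, swa and zpg. The members with the highest values were grk, an EGFR ligand gene, at 4.10 ± 0.060 (SD, n = 3), ovo at 3.55 ± 0.12 and Rbp9 at 2.88. At the stricter level 1 of 15 was above. The follicle list and the germline list differed by 33.3 percentage points in their shares, which did not pass (Fisher's exact test, adjusted p = 0.14). Without replicate 1 the difference was 13.3 percentage points, with 6 of 15 against 4 of 15 (Fisher's exact test, adjusted p = 0.70).

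Eggshell and yolk genes, products of differentiated follicle cells, were below background in 16 of 21 cases, with 5 above, also when adjusted over the list alone. Their share of 23.8% did not pass against other genes (Fisher's exact test, adjusted p = 0.097). The eggshell gene dec measured 6.90 ± 0.28 (SD, n = 3), the vitelline membrane gene Vm34Ca 3.61 on every array and tsl 3.21. Cp7Fc, Femcoat and Vm32E measured 2.39.

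**Figure D2:**
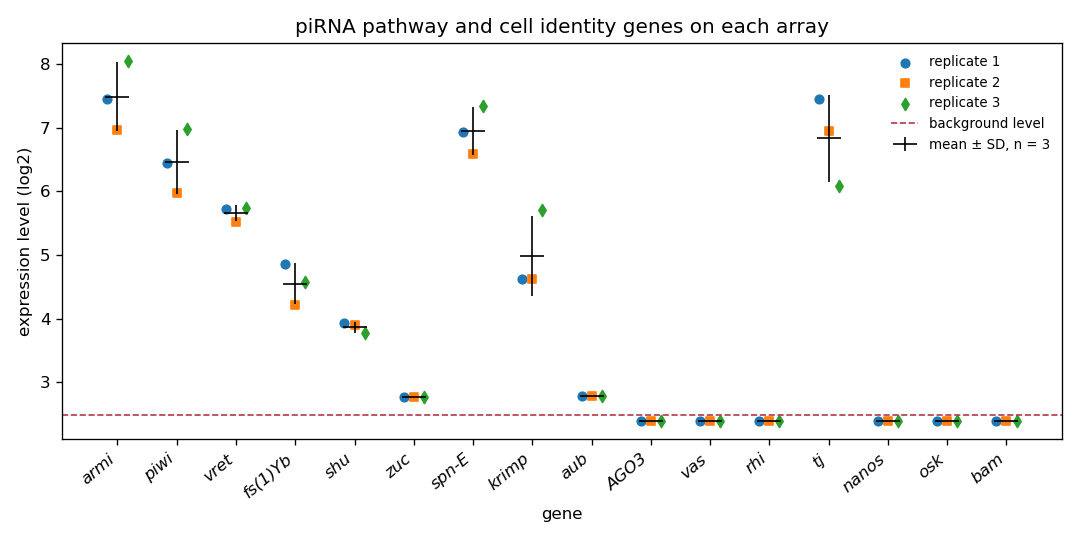
Log2 expression level (y axis) of 16 genes (x axis) on each of the 3 arrays, with the mean and SD in black and the background level dashed. armi, piwi, spn-E and tj lie above 5 on every array, while AGO3, vas, rhi, nanos, osk and bam lie at 2.39.

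Genes of small RNA pathways and of growth had high shares above background. Of 12 microRNA and siRNA genes, 11 were above (adjusted p = 0.0099 by Fisher's exact test) and 12 when adjusted over the list alone; Tudor-SN measured 6.67 ± 0.19 and me31B 6.63 ± 1.33, with pasha at 2.70 and pcm at 2.51 (SD, n = 3). All 17 cell cycle genes were above, also over the list alone (Fisher's exact test, adjusted p = 3.3e-05), among them PCNA at 9.53 ± 0.23 and Mcm6 at 7.32 ± 0.17, with fzr at 3.50 ± 0.019 and CycE at 2.86 ± 0.17. Of 41 ribosomal protein genes, 35 were above on either adjustment (Fisher's exact test, adjusted p = 1.8e-05), with RpL23 at 12.90 ± 0.22 and RpL41 at 12.62 ± 0.14. RpS28-like and RpS28a measured 2.39; ribosomal protein genes have close paralogs and pseudogenes, so their values are uncertain.

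Each signalling pathway was compared with all other genes, and the pathways were not compared with each other. All 8 EGFR pathway genes were above (Fisher's exact test, adjusted p = 0.0099), with the ligand gene spi at 6.67 ± 0.30, drk at 5.98 ± 0.29, aos at 2.79 and Krn at 2.70 (SD, n = 3). Of 9 Hedgehog pathway genes 8 were above (adjusted p = 0.039), with cos at 6.03 ± 0.00059, dlp at 4.34 ± 0.024, boi at 3.37 ± 0.11 and the unresolved smo at 2.98 ± 0.30. Of 9 Notch pathway genes 8 were above (adjusted p = 0.039), with the glycosyltransferase gene fng at 7.44 ± 0.22, E(spl)m3-HLH at 7.32 ± 0.64, neur at 2.57 ± 0.033 and E(spl)m7-HLH at 2.42. The EGFR call was lost at the stricter level (adjusted p = 0.26), with the highest background gene as level (0.16), without replicate 1 (0.073) and without replicate 2 (0.080), and the Notch call under 12 of 18 alternatives. In the BMP pathway 8 of 10 were above, which did not pass (adjusted p = 0.10, but 0.022 without replicate 3), with gbb at 6.58 ± 0.41, put at 6.25 ± 0.22, wit at 2.63 and the ligand gene dpp at 2.39. JAK-STAT had 2 of 5 above, the receptor gene dome at 5.75 ± 0.017 and Stat92E at 5.23 ± 0.52, while upd1 and et measured 2.39. Only 3 of 14 listed Wnt genes were measured. Of these, 2 were above, Axn at 3.56 ± 0.0038 and Wnt6 at 2.85 ± 0.19, with nkd at 2.46 ± 0.052. The ecdysone list had 4 of 8, with usp at 5.15 ± 0.057, Hr39 at 4.67 ± 0.33, and Hr3 and Hr4 at 2.39; without probe sets of shared sequence Hr39 was below background. Adjusted over the list alone, 8 EGFR, 9 Hedgehog, 8 Notch, 9 BMP, 2 JAK-STAT, 2 Wnt and 4 ecdysone genes were above.

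All 10 sex determination and dosage compensation genes were above background, also over the list alone (Fisher's exact test, adjusted p = 0.0033), with dsx at 7.21 ± 0.50, tra2 at 5.87 ± 0.092, msl-2 at 2.57 and mle at 2.57 ± 0.0042 (SD, n = 3). The call was lost at the stricter level with 5 above (adjusted p = 0.26), with the highest background gene as level (0.34), at the 99th percentile (0.21), with testis genes as background (0.20) and without probe sets of shared sequence (0.071; Fisher's exact test). Only 4 of 8 listed Hox genes were measured, and lab, Ubx, abd-A and Abd-B were not analysed here. None of the 4 was above, with Dfd at 2.43 and Antp, pb and Scr at 2.39. None of the 6 measured fat body and gut genes was above, with Jon65Aiii at 2.43, Lsp2 at 2.40, and Fbp2 and Jon25Bi at 2.39. Adjusted p-values were 0.21 and 0.075 (Fisher's exact test); with probe sets of several genes kept, 0 of 8 fat body and gut genes were above and the list passed (0.026). At the reported settings, no member of either list was above when adjusted over the list alone.

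Markers of other cell types were measured as well. Of 13 testis genes 1 was above, a smaller share than that of other genes (Fisher's exact test, adjusted p = 0.015; 0.15 at the stricter level). That gene was mia at 2.52; twe was unresolved at 2.69 ± 0.17, and sa and Tektin-A measured 2.39 (SD, n = 3). Of 11 hemocyte genes 6 were above and 1 at the stricter level, with Pxn at 4.43 ± 0.27 and crq at 3.54 ± 0.062, and with Hml and eater at 2.39. Of 9 neuronal and glial genes 4 were above and 0 at the stricter level, with the glial receptor gene moody at 4.32 ± 0.59, elav at 2.72, and nrv3 and Appl at 2.39. Of 6 muscle genes 2 were above and 0 at the stricter level, with Mlc2 at 3.25 ± 0.055, Prm unresolved at 3.10 ± 0.71, and with up and Act88F near the lowest value. Of 5 antimicrobial peptide genes 2 were above and 0 at the stricter level, with Drs and CecB at 2.54 and Def and Mtk at 2.39. The hemocyte, neuronal, muscle and antimicrobial shares did not pass (Fisher's exact test, adjusted p = 0.91, 1, 0.86 and 1), and the counts adjusted over the list alone were 6, 4, 2 and 2.

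**Figure D3:**
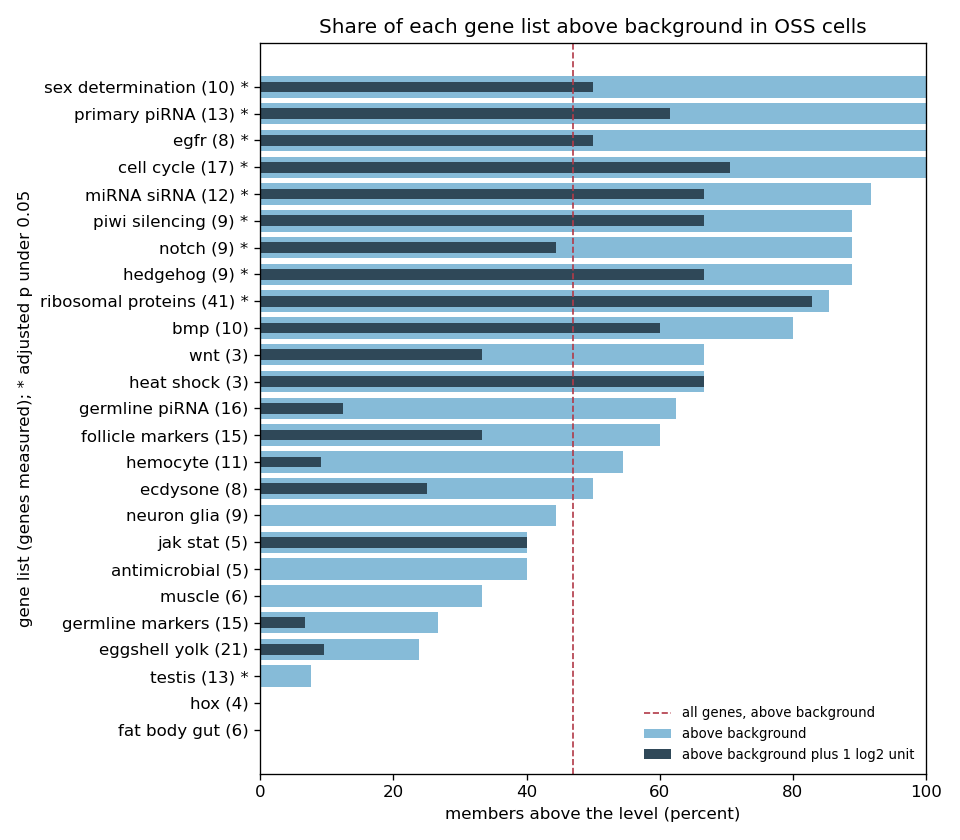
Percent of measured members (x axis) above background (light bars) and above the stricter level (dark bars) for 25 gene lists. The y axis gives the genes measured in parentheses. The dashed line is the 47.0% of all genes above background and refers to the light bars only. At the stricter level 3028 of 11870 genes were above. Primary piRNA, cell cycle, EGFR and sex determination genes reach 100%, and fat body and gut and Hox genes 0%.

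Of the 3 measured genes of the heat shock list, Hsp26 at 10.58 ± 1.12 and Hsp27 at 6.50 ± 0.63 were above background and Hsp68 was unresolved at 4.41 ± 1.18 (SD, n = 3; 2 of 3 above, Fisher's exact test, adjusted p = 0.79; 3 when adjusted over the list alone). The genes above background with the largest SD were CG3168 at 7.06 ± 1.52, the chitin-binding gene Gasp at 5.19 ± 1.48, Drat at 7.63 ± 1.40, the nucleolar gene mod at 7.15 ± 1.39 and me31B at 6.63 ± 1.33. Without replicate 1, me31B, CycE, Wnt6, neur, moody, Drs, CG3168, Gasp and mod were no longer called (limma, adjusted p from 0.051 to 0.16), and without replicate 2 neither were CycE, Wnt6, CG3168 and Drat (0.053 to 0.093). Without replicate 3, Gasp was not called (0.055), Hsp68, smo and Prm were above background (0.017, 0.00084 and 0.025) and nkd below it (0.0053).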

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

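These results came to notice because signal lay in probe sets outside the gene results. All tests on them were chosen after the data were seen. Of 4720 probe sets with no gene in the annotation used, controls left out, 775 (16.4%) were above background, and 60 had means over log2 10. Of 402 probe sets with several genes, 168 (41.8%) were above background.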

How the results depend on the processing

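Foreign and tag controls as background, the pooled spread, the highest background gene as level and the stricter level 1 log2 unit above background were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because all samples belong to 1 group. The planned comparison with 3′ UTR length was not run, the filter on dim probe sets removed 0 of them, and the pseudocount did not apply.

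Over 168 results and 2986 values under 18 alternatives, 2831 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. Genes above background numbered 4440 to 6365, of which 4440 to 5582 were called in the reported test too, except at the stricter level with 3028, all of them called in the reported test. Leaving out 1 array gave 5215 to 5545. The primary piRNA list passed under every alternative, and so did the difference of its share from that of the germline piRNA list. With foreign and tag controls as background, 5497 genes were above.

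For the Piwi silencing list, 88.9% of genes were above background but the list missed the threshold with odorant receptors (Fisher's exact test, adjusted p = 0.10), bacterial controls (0.099) and the 90th percentile (0.10), where more of the other genes were above. With probe sets free of shared sequence its share was 83.3% of 6 genes (0.20), and without 1 array 77.8% to 88.9% (0.035 to 0.11). Of the 19 other lists, 8 passed, against 5 with the highest background gene as level and 4 at the stricter level. The follicle and germline lists differed by 46.7 percentage points with bacterial controls, which passed (Fisher's exact test, adjusted p = 0.027). Their difference did not pass under any other alternative. It was smallest without replicate 1, at 13.3 percentage points (Fisher's exact test, adjusted p = 0.70). Changes of the 19 other lists numbered 24, and among values of single genes 45 lost a call in the same direction, 11 gained one and 66 changed side of the level or, for Gr39a, came to lie on it; the cause was not tested.

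Genes near background changed side with the level, as its construction implies; values are log2 units above it. At the stricter level these lay below: aos (-0.70), aub (-0.69), boi (-0.12), CecB (-0.95), CycE (-0.62), daed (-0.54), Drs (-0.95) and elav (-0.77). Further values at this level were those of Gr39a (-0.70), Gr61a (-0.88), Krn (-0.78), mia (-0.97), Mlc2 (-0.24), mle (-0.92), msl-2 (-0.91) and neur (-0.91). Further values at this level were those of Panx (-0.42), pasha (-0.79), pcm (-0.97), Rbp9 (-0.61), smo (-0.51), SoYb (-0.84), tsl (-0.27) and tud (-0.087). Further values at this level were those of twe (-0.79), wde (-0.78), wit (-0.86), Wnt6 (-0.64) and zuc (-0.71). With the highest background gene, Gr39a, as level they were CecB (-0.25), Drs (-0.25), elav (-0.069), Gr39a (0 by construction), Gr61a (-0.18), Krn (-0.087), mia (-0.27) and mle (-0.22). Further values at this level were those of msl-2 (-0.22), neur (-0.22), pasha (-0.091), pcm (-0.28), SoYb (-0.14), wit (-0.16) and zuc (-0.014). At the 99th percentile they were CecB (-0.069), Drs (-0.063), mia (-0.086), mle (-0.038), msl-2 (-0.032), neur (-0.032) and pcm (-0.092). With testis genes as background they were CecB (-0.053), Drs (-0.047), mia (-0.070), mle (-0.021), msl-2 (-0.015), neur (-0.015) and pcm (-0.076). Genes that moved above the level were, at the 90th percentile, Dfd (0.0054) and Jon65Aiii (0.012). With odorant receptors they were Dfd (0.0036) and Jon65Aiii (0.011). With bacterial controls they were Dfd (0.013), E(spl)m7-HLH (0.0051) and Jon65Aiii (0.020). Without shared-sequence probe sets Hr39 fell to a value below background, -0.098. Of simulated genes set 0.25 log2 units above background 74% were called, a share that may be too high because some simulated SDs were 0. No genes closer to the level were simulated.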

Other observations

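The tests here were chosen after the results were seen, except those of 1 probe set only and of array scaling. Families picked by symbol added housekeeping groups to the profile (limma calls, Fisher's exact test adjusted over 8 families). All 69 mitochondrial ribosomal protein genes were above background (median 5.37, adjusted p = 1.6e-22), as were all 8 subunits of the CCT chaperonin, a folding machine for actin and tubulin (median 9.15, adjusted p = 0.0032). Of 40 proteasome genes 27 were above (adjusted p = 0.012), with Prosbeta5 at 8.38 and Rpn11 at 8.02, while the paralogs Prosalpha3T, Prosalpha4T1 and Prosalpha6T lay at the lowest value of 2.39. Of 66 oxidative phosphorylation genes 46 were above (adjusted p = 0.00043), and those below it included the paralogs COX7AL, ND-20L and UQCR-14L at 2.39, but also ND-B8 at 2.39 and UQCR-11 at 2.41.

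Families with few members above background were cuticle proteins, with 7 of 66 (adjusted p = 1.0e-09), odorant-binding proteins, with 1 of 47 (adjusted p = 1.9e-11), and cytochromes P450, with 20 of 81 (adjusted p = 9.0e-05; Fisher's exact test). At the stricter level 1 cuticle gene, Cpr67Fa1 at 6.19, was above, as were 0 odorant-binding genes and 7 P450 genes. The P450 genes with the highest values were Cyp18a1 at 7.47, which encodes an ecdysteroid-inactivating enzyme, Cyp4p2 at 6.92 and Cyp6a13 at 6.46. V-ATPase genes were not shown to differ from the rest, with 16 of 31 above (adjusted p = 0.72), and Vha16-1 and Vha100-2 measured 9.17 and 8.72. The ribosomal protein paralog RpS5b measured 7.39 ± 0.54 and RpS19b 3.03 ± 0.078 (SD, n = 3).

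The first pattern was signal from germline piRNA factors in a somatic line, with 10 of 16 members above background. For spn-E and krimp, germline cells in the cultures were examined by the germline markers, of which 1 of 15, grk, was above the stricter level. That count cannot decide the question, because the test was set after the values were seen and probe sets differ in affinity. For the other 8 called members germline cells stay open too: 4 of the 15, grk, ovo, Rbp9 and gcl, were above background. Of the other markers, 10 were below background, among them osk, nanos, orb, bam, bcd, swa and zpg, and bgcn was unresolved. The germline piRNA genes AGO3, vas and tej lay at the lowest value of 2.39 on every array. A background level set too low stays open, since only 2 of the 10 called members, spn-E and krimp, were above the stricter level. Cross-hybridisation stays open: only 1 called member, tapas, had 2 probe sets above background, qin had 1 of 2 above, and each of the others had 1 probe set; no biological explanation was tested.

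The second pattern was identical values on all 3 arrays. A floor on low values cannot be the whole cause, since 11.8% of the 3378 probe sets with means over log2 4 were identical on all 3 arrays. A summary that takes medians over the arrays predicts many values shared by exactly 2 arrays, and 26.1% of the other probe sets over log2 4 were; it is a candidate explanation. No biological explanation was tested.

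The third pattern was the spread of the 3 listed heat shock genes between the arrays. The small heat shock gene l(2)efl measured 10.94 ± 0.054 (SD, n = 3). Its values in replicates 1 and 2 were identical, so this SD may understate the error. Replicates 1, 2 and 3 gave 11.75, 10.48 and 9.52 for Hsp26, 7.20, 6.34 and 5.97 for Hsp27, and 5.45, 4.65 and 3.13 for Hsp68. A fall in that order was not particular to heat shock genes. In the same replicates tj measured 7.45, 6.96 and 6.09. An eIF-4a control probe set measured 11.25, 10.66 and 10.13. A GAPDH control probe set was instead lowest in replicate 2, with 10.19, 8.64 and 8.98. A scaling shift shared by all genes is argued against, since the median of genes above background in replicate 1 minus that in replicate 3 was -0.019 log2 units. A scaling difference that depends on intensity was not tested, and the scaling of the deposited values was not given in the sources used here. RNA quality stays open. The 5′ minus 3′ difference was lowest in replicate 3 for 3 of 4 control transcripts, but higher in replicate 2 than in replicate 1 for 3 of 4. These 3 were the mRNAs Act5C (-0.011, 0.20 and -0.72 in replicates 1, 2 and 3), GAPDH (-0.72, -0.42 and -0.78) and eIF-4a (-1.31, -1.14 and -2.31). The exception in both counts was 18S rRNA (-3.09, -3.36 and -2.87), which is not an mRNA. Each transcript gives 1 value per array with no spread. A difference between the samples in stress at harvest was not tested, because the labels give no such variable. The labels also do not say whether the samples were separate cultures.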
